A study of Homo sapiens with 4 samples.

How the data were processed

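Total RNA from U87MG cells grown in multiwell plates was labelled with biotin and hybridised to Affymetrix PrimeView 3' expression arrays, 2 arrays for cells with the control vector and 2 for cells with the miR-490 vector, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The deposited values are log2 expression per probe set, made by the authors with RMA, per the submitters' processing notes; RMA corrects background, makes the distributions of the arrays alike and summarises the probes of a set. The RMA software, its version and its settings are not given in the sources used here. The values have 2 decimals, range from 1.72 to 14.24 and are not centred per probe set; the array medians are 5.15, 5.16, 5.16 and 5.17, and the quartiles 3.16 to 3.20 and 7.39 to 7.40. Because RMA equalises the arrays, a shift of most transcripts in 1 direction cannot be seen, and compression of low signals can understate differences of dim genes. Detection calls, scan dates and chip control probe sets were not used here, so batches were not tested, and no genome build applies to these values. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.0725.

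Of 49293 probe sets, 44988 have 1 gene symbol in the platform annotation, 1832 several and 2473 none. The Entrez IDs of 44961 single-gene probe sets matched the RefSeq gene table and took their current symbols from it. For each of 18132 genes, the single-gene probe set with the highest mean over the 4 arrays was used; 11734 genes had more than 1 probe set. No filter on dim genes was applied in the reported fit.

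The miR-490 vector was compared with the control vector in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend, no block; 2 residual degrees of freedom and 2.46 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 29 lists. The lists were NF-kB inflammatory, G2/M mitosis, G1/S replication, endoplasmic reticulum and integrated stress, immediate early, reported miR-490 targets, telomere maintenance, nonsense-mediated decay, microRNA machinery, TGF-beta, mesenchymal matrix, interferon-stimulated, p53, DNA repair, heat shock, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, autophagy and lysosome, apoptosis, metallothioneins, Wnt targets, glioma stem and neural progenitor genes, markers of epithelial, leukocyte, neural and endothelial cells, and the 9p21 genes. They hold 511 genes, of which 469 were measured and 42 were not analysed here. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined. Figures were drawn with matplotlib 3.10.9.

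The rule for named genes took, when fewer than 10 genes passed, the 10 higher and 10 lower genes with the smallest p among genes above the median level, skipping predicted or unnamed transcripts; of each list described, up to 4 members with the smallest p; and, whatever their result, TERF2, TNKS2, SMG1, TGFBR1, TGIF2, HMGA2, CDK1, CCND1 and CHRM2. For no named gene did another probe set above the array median differ in sign at an unadjusted p under 0.05.

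The fit was tested on simulated arrays of the same 18132 genes over 20 runs, with 50 genes changed at each size for the comparison of the miR-490 with the control vector. It recovered 0.1% of genes changed by a log2 value of 0.25, 3.9% at 0.5, 78.2% at 1 and 94.5% at 2, with a median of 5 false calls per run. The list test was tested over 100 runs with independent genes: 4 runs had a false list, and a fall of the NF-kB list by 0.1 was found in 85 runs and by 0.2 in 100. Genes that vary together, which the simulation left out, make the list test less strict.

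Alternatives were quantile normalisation, centring on array medians, an intensity trend with and without a robust prior, genes above the median level only, the mean of a gene's probe sets, all probe sets, an ordinary test per gene, an added fold threshold, each replicate left out, the replicate number as a block, camera with an estimated correlation, camera on ranks and fry. A planned test of 3' UTR seed sites was not run, since 3' UTR sequences were not used here, and values of chip control probe sets were likewise not analysed here.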

Results

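Gene expression was measured in U87MG, an established human glioma cell line, after transfection with a plasmid that overexpresses the microRNA miR-490 or with its empty control plasmid. A microRNA is a short RNA that pairs with messenger RNAs and lowers their stability or translation. RNA was taken 48 h after transfection, and 2 PrimeView 3' expression arrays per group were run, each from 100 ng of total RNA. The deposited log2 values cover 49293 probe sets, from which 18132 genes were tested. The array medians lay between 5.15 and 5.17. The control arrays correlated with each other at r = 0.9983 across genes and the miR-490 arrays at 0.9985, while pairs from different groups gave 0.9982 to 0.9984. The SD of the log2 difference between arrays was 0.156 within the control pair, 0.147 within the miR-490 pair and 0.148 to 0.161 between groups, so arrays of different groups lay about as far apart as replicates. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

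The comparison asks which transcripts differ when miR-490 is overexpressed. The list of inflammatory genes driven by NF-kB, a transcription factor of cytokine responses, fell in the miR-490 arrays (median log2 fold change -0.22; camera adjusted p = 7.52e-15, and adjusted p = 0.743 with an estimated correlation). The list of mitosis genes passed in the other direction with a median of 0.10 and no single member past its threshold (camera adjusted p = 0.000152, adjusted p = 0.743 with an estimated correlation, and 0.158 without control replicate 2). A list of stress-response genes passed as lower with a median of -0.05 (camera adjusted p = 0.0184, and adjusted p = 0.743 with an estimated correlation). No single gene passed the threshold over all genes, and the largest difference was 1.55-fold over the 1 probe set used per gene and 1.60-fold over all probe sets. With limma and Benjamini-Hochberg adjustment over 18132 genes, 0 genes had an adjusted p under 0.05, and the smallest adjusted p was 0.786. At an unadjusted p under 0.01 there were 170 genes, where chance gives 181. At an unadjusted p under 0.05 there were 1121 genes, 599 higher and 522 lower, where chance gives 907. Regrouped into pairs that mixed the vectors, the arrays gave 923 and 1005 genes at that level (limma). An ordinary test without moderation also gave 0 genes past the adjusted threshold. It covered 18080 genes, since 52 genes without spread within the groups were left out. Of these, 1036 had an unadjusted p under 0.05, where chance gives 904. With 1 array left out, the limma count at that level was above chance without either control array and below it without either miR-490 array. The groups did not overlap in 5902 genes, 32.6% of the total, where chance gives 33.3%. With 2 arrays against 2, the smallest exact two-sided permutation p is 0.333 for any 1 gene.

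The genes above the median level with the smallest p are given as values, since none passed (adjusted p = 0.786 for each, limma). Among those higher with miR-490, SPINK1, a trypsin inhibitor, was at 6.71 ± 0.0071 against 6.24 ± 0.11 in controls (log2, SD, n = 2), a fold of 1.39. EGR1, FOS and ATF3, transcription factors of the immediate early response, were at 1.32, 1.27 and 1.31 times the control level. CEMIP and HYAL3, both linked to hyaluronan breakdown, were at 1.24 and 1.27 times, and the growth factor PGF at 1.23 times. SPAG5, a spindle protein, was at 1.21 times, FZR1, an activator of the anaphase-promoting complex, at 1.24 times, and TENT5C at 1.19 times. On the lower side, the chemokines CXCL2 and CXCL8 were at 0.669 and 0.727 of the control level, and the cytokines IL6 and IL1B at 0.755 and 0.760. NFKBIZ, an NF-kB cofactor, was at 0.787, the matrix proteases MMP3 and MMP7 at 0.747 and 0.771, and RFTN1 at 0.776. HBEGF, a ligand of the EGF receptor, was at 0.807 and the checkpoint kinase gene CHEK2 at 0.753. Of these 20 genes, 14 had other probe sets, 30 in all, of which 22 had the sign of the set used and 8 the opposite sign. In 7 genes, RFTN1, TENT5C, CEMIP, CHEK2, HBEGF, IL6 and SPAG5, every other set had a log2 fold change within 0.1 of 0. The other sets of ATF3, EGR1, FZR1 and MMP7 had both signs, while those of FOS gave 0.48 to 0.67, those of CXCL8 -0.50 and -0.455, and that of CXCL2 -0.585.

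The NF-kB inflammatory list fell in the miR-490 arrays (camera against all other genes, adjusted p = 7.52e-15 over 29 lists). With an estimated correlation the call was lost, at an adjusted p = 0.743 (unadjusted p = 0.0257). All 19 of its measured genes had lower means, with a median log2 fold change of -0.22. CXCL8, a neutrophil chemokine, went from 10.96 ± 0.050 to 10.50 ± 0.021 (log2, SD, n = 2), and IL1B from 9.68 ± 0.0071 to 9.28 ± 0.014. IL6 went from 9.22 ± 0.064 to 8.81 ± 0.014 and CXCL2 from 8.76 ± 0.12 to 8.18 ± 0.11. Adjusted over the list alone, 9 of the 19 genes fell, and these 4 had an adjusted p of 0.0108 each (limma); over all genes 0 fell. The leukocyte marker list, which would show immune cells, had a median log2 fold change of -0.13 over 11 genes and did not pass (camera adjusted p = 0.267).

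**Figure D1:**
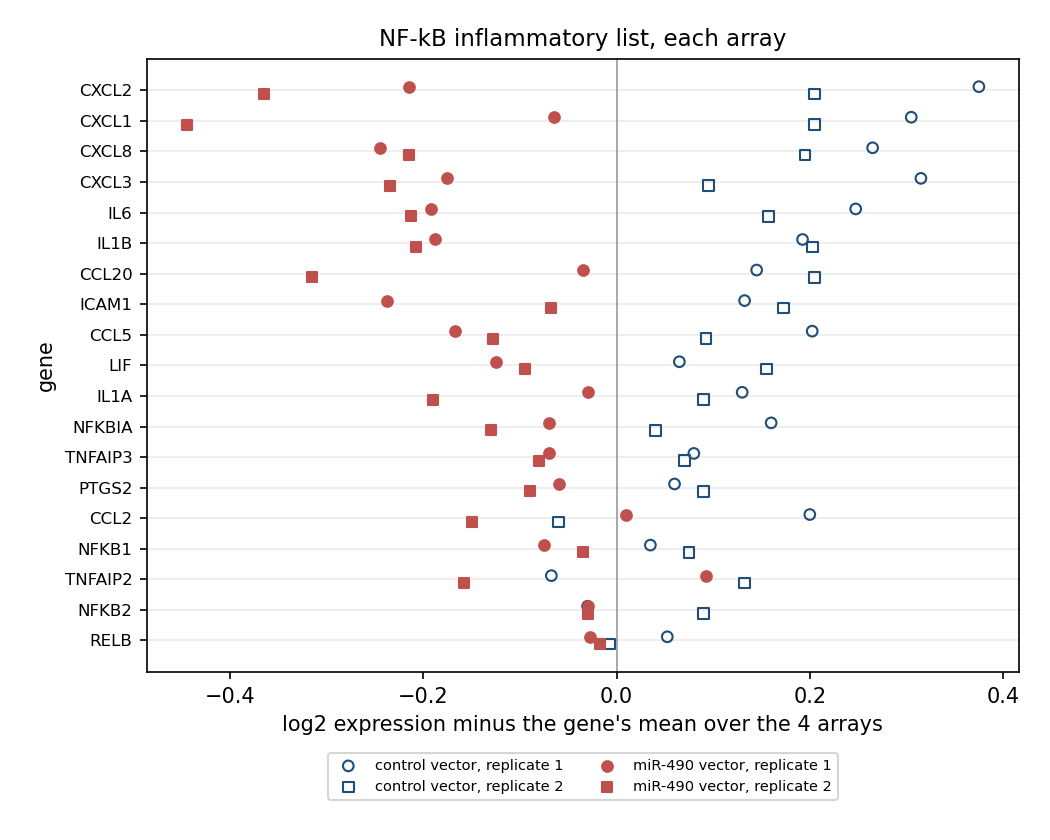
Log2 expression of each of the 19 measured NF-kB list genes on each array, minus that gene's mean over the 4 arrays; open blue symbols are control arrays, filled red symbols miR-490 arrays, circles replicate 1 and squares replicate 2, and the small vertical shift only separates symbols. CXCL2, at the top, has the lowest log2 fold change, -0.58, and RELB, at the bottom, the one nearest to 0, -0.045.

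Genes of the G2 phase and mitosis passed as a list, as higher with miR-490 (camera adjusted p = 0.000152). The call was lost with an estimated correlation, at an adjusted p = 0.743, and without control replicate 2, at an adjusted p of 0.158 with a median of 0.0625. Of its 26 measured genes, 23 had higher means with miR-490, with a median log2 fold change of 0.10. MKI67, a marker of proliferating cells, was at 7.65 ± 0.12 against 7.42 ± 0.042 in controls (log2, SD, n = 2). CCNB1, the cyclin of mitotic entry, was at 8.48 ± 0.0071 against 8.30 ± 0.071, CDC25C, which activates the mitotic kinase, at 1.13 times the control level, and CDC20 at 1.10 times. Over all genes and adjusted over the list alone, 0 members rose or fell, the smallest list-alone adjusted p being 0.316 (limma). The G1/S and replication list had 20 of 27 measured genes lower and a median of -0.045, and it did not pass (camera adjusted p = 0.0928). Without control replicate 2 it passed as lower, at an adjusted p of 0.00527 and a median of -0.075, and without control replicate 1 the values were 0.907 and -0.01. Its members ORC1, of the origin recognition complex, and CCNE2, a cyclin of S phase entry, were at 0.838 and 0.877 of the control level, CDC6 at 0.940 and E2F1 at 0.923.

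The list of endoplasmic reticulum and integrated stress genes fell (camera adjusted p = 0.0184). With an estimated correlation the call was lost, at an adjusted p = 0.743. Of its 21 measured genes 16 had lower means, with a median log2 fold change of -0.05. The members with the smallest p included PSAT1, an enzyme of serine synthesis, which was at 9.79 ± 0.042 against 10.16 ± 0.092 in controls (log2, SD, n = 2). SLC7A11, the cystine transporter, was at 0.807 of the control level and ASNS, asparagine synthetase, at 0.841, while ATF3 was at 1.31 times. The other probe sets of PSAT1 and ASNS were all negative, whereas those of SLC7A11 had log2 fold changes of -0.18 and 0.03. No member passed adjusted over the list alone (smallest adjusted p 0.0515, limma) or over all genes. The list's call was also lost on quantile-normalised values (adjusted p 0.0965), on ranks (0.0624), and without control replicate 1 (0.482), miR-490 replicate 1 (0.185) or miR-490 replicate 2 (0.0807), and without control replicate 2 the adjusted p was 0.00228 with a median of -0.105.

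Immediate early genes, which respond within minutes to growth factors and stress, did not pass as a list of 14 (median log2 fold change 0.04, camera adjusted p = 0.273). Adjusted over the list alone, 3 of them rose, and over all genes 0. EGR1 was at 7.34 ± 0.042 against 6.94 ± 0.092 (log2, SD, n = 2; list-alone adjusted p 0.0279, limma), FOS at 1.27 times the control level (0.0279), and ATF3 at 6.93 ± 0.13 against 6.54 in both control arrays (0.0291). MYC was at 0.877 of the control level (0.0784).

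Messenger RNAs reported elsewhere as miR-490 targets did not pass as a group. Of 14 measured genes, 8 had lower and 6 higher means, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.721). The list's median log2 fold change was -0.04 and its mean 0.0082, and the test's direction was down. The member with the smallest p, FOS, lay opposite to the lowering a microRNA gives its targets, with a log2 fold change of 0.34 (95% interval 0.17 to 0.51; list-alone adjusted p 0.0559, limma). HMGA2, a chromatin protein, had a log2 fold change of -0.18 (95% interval -0.32 to -0.030; adjusted p 0.786, limma), and TNKS2, a tankyrase, -0.17 (-0.32 to -0.014; 0.786). TGFBR1, a receptor of TGF-beta, had -0.11 (-0.28 to 0.062; 0.826) and CCND1, cyclin D1, -0.095 (-0.26 to 0.068; 0.835). TERF2, which encodes a telomere-binding protein, had 0.045 (-0.10 to 0.19; 0.929), SMG1, a kinase of nonsense-mediated decay, 0.065 (-0.22 to 0.35; 0.957), and CDK1 0.070 (-0.13 to 0.27; 0.916). TGIF2, a repressor in TGF-beta signalling, was dim and had 0.28 (0.043 to 0.53; 0.786). CHRM2, the gene that hosts miR-490, was also dim, at a mean level of 2.53, with 0.20 (-0.079 to 0.49; 0.812). Other probe sets of HMGA2 were negative in 4 of 5 cases (-0.43 to 0.245), and all 3 others of TNKS2 and of CCND1 were negative. Those of TGFBR1 and CDK1 had both signs, those of TGIF2 (-0.185) and SMG1 (-0.015) the opposite sign, and those of TERF2 (0.165) and CHRM2 (0.03) the same sign. The microRNA itself was not analysed here, so the arrays give no check of its overexpression.

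**Figure D2:**
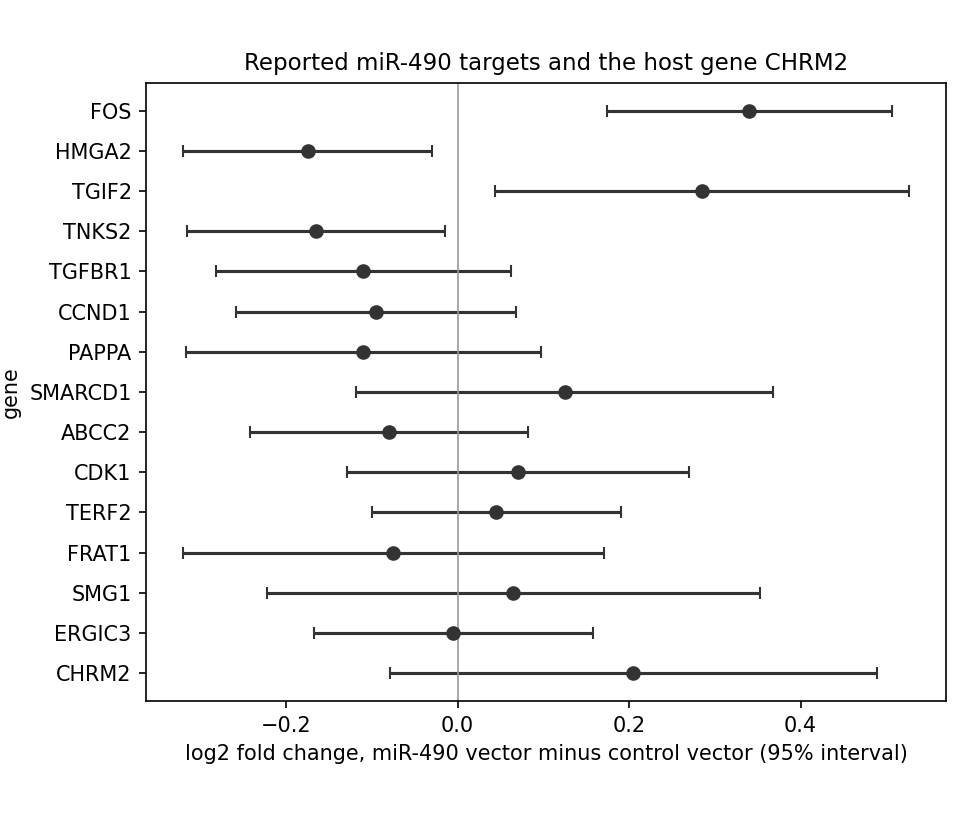
Log2 fold change, miR-490 vector minus control vector, of the 14 measured reported miR-490 targets, ordered by p, and of the host gene CHRM2; points are estimates from 2 arrays per group and bars their 95% intervals from limma. The intervals of TNKS2 and HMGA2 lie below 0 and those of FOS and TGIF2 above 0 before any adjustment, and no adjusted p passes.

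Lists of processes tied to these targets did not pass either. The telomere maintenance list had 15 of 26 genes higher and a median log2 fold change of 0.013 (camera adjusted p = 0.721), with SMG5 at 1.15 and ATRX at 1.12 times the control level. Factors and substrates of nonsense-mediated decay had a median of 0.04 over 14 genes (0.644), with TBL2 at 0.898 and SNHG12 at 1.07 times. The other probe sets of TBL2 had log2 fold changes of 0.02 and 0.03. The microRNA machinery had 10 of 13 genes higher and a median of 0.03 (0.472), with AGO1 at 1.14 times. TGF-beta signalling genes and targets had 13 of 19 genes lower and a median of -0.015 (0.721), with TGFB2 at 0.874 and ID3 at 1.09 times. The other probe set of TGFB2 had a log2 fold change of 0.025. Mesenchymal and matrix genes had 16 of 22 lower and a median of -0.038 (0.0791), with POSTN at 0.895, COL5A1 at 0.898, MMP9 at 0.829 and ZEB2 at 0.871. In each of these 5 lists 0 members passed over all genes or adjusted over the list alone.

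Both groups were transfected with a plasmid, so a response to transfection common to both cannot be seen in this comparison. Among responses that a transfected plasmid can set off, interferon-stimulated genes had a median log2 fold change of 0.01 and a mean of -0.016 over 27 genes, and the test's direction was down (camera adjusted p = 0.721). IFIH1, a sensor of double-stranded RNA, was at 0.798 of the control level, IFIT2 at 0.871 and PARP9 at 1.07 times. The p53 target list had 11 genes higher and 11 lower (0.664), with GDF15 at 0.838 and DDB2 at 1.11 times, and the DNA repair list 11 of 17 higher (0.644), with CHEK2, its member with the smallest p, at 0.753 (list-alone adjusted p 0.0529, limma) and ATM at 1.19 times, while the 4 other probe sets of ATM gave log2 fold changes of -0.08 to 0.105. Markers of other cell types did not pass: epithelial genes had a median of 0.0075 (0.644), markers of neurons and glia -0.025 (0.644), and endothelial markers -0.015 with a mean of -0.0057 and a test direction of up (0.961). Genes of the 9p21 region, reported as deleted in this line, were dim in both groups, with mean levels of 3.50 for CDKN2A, 2.98 for CDKN2B and 4.62 for MTAP, and did not pass as a list (0.721).

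**Figure D3:**
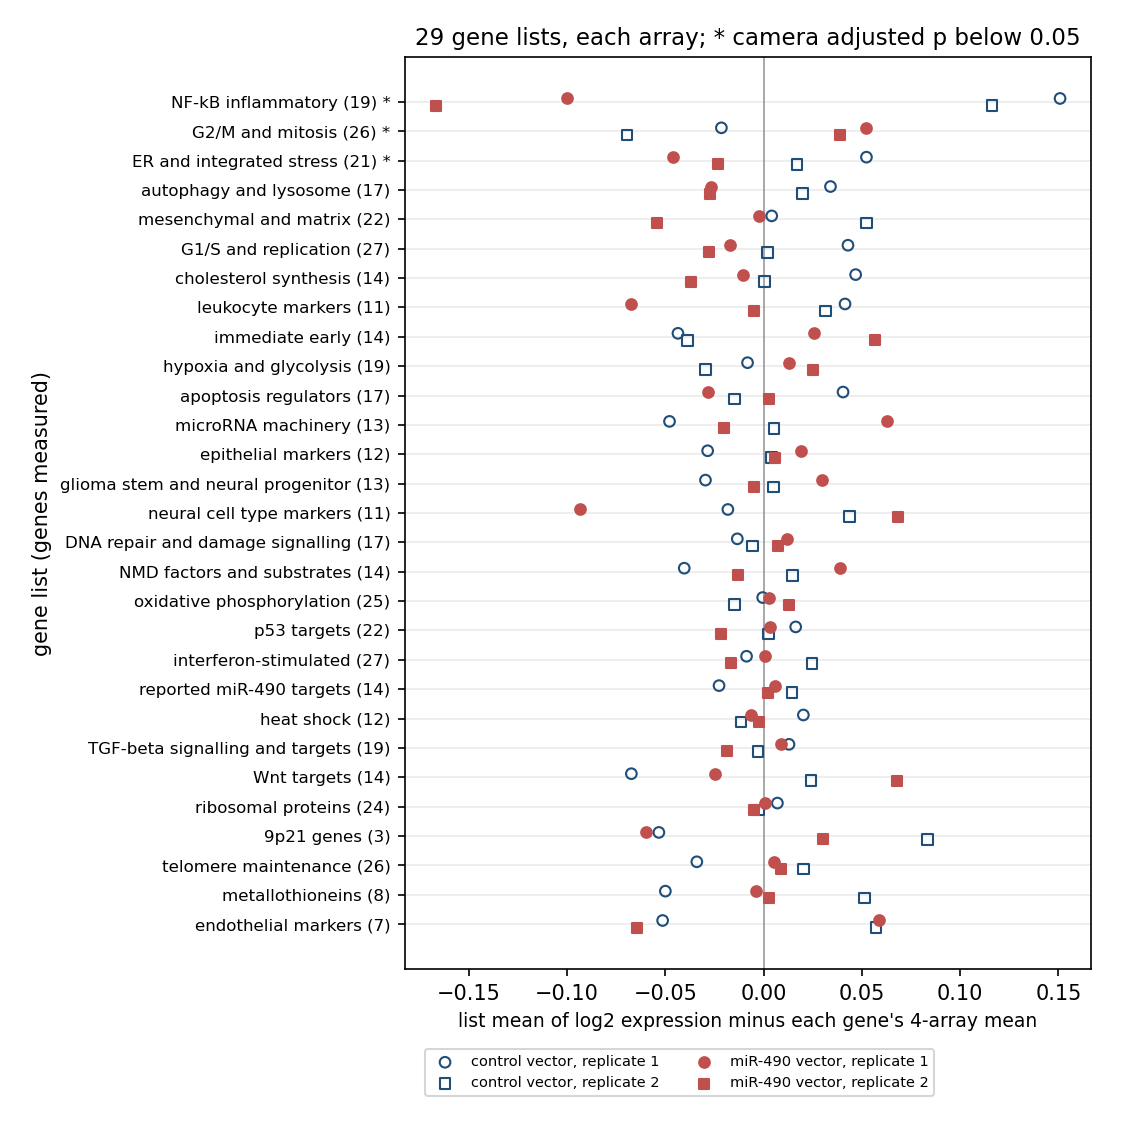
For each of the 29 lists and each array, the list's mean of log2 expression minus each gene's 4-array mean, with the number of measured genes in brackets, ordered by camera p; symbols are as in the plot of NF-kB genes and an asterisk marks an adjusted p under 0.05. The NF-kB list lies at 0.15 and 0.12 in the control arrays and at -0.10 and -0.17 in the miR-490 arrays, apart from the other lists.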

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

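The count of genes past the adjusted threshold was 0 in every alternative run, with the smallest adjusted p at 0.13 under a trend with a robust prior; all probe sets gave 0 with 2537 at an unadjusted p under 0.05, where chance gives 2465, and genes above the median level gave 641, where chance gives 453. The number of lists past the threshold was 3 as reported, 7 with an intensity trend, 5 with the mean of a gene's probe sets, and 0 with an estimated correlation or with fry. Camera with an estimated correlation refers its statistic to the 2 residual degrees of freedom, which by construction makes it stricter; it gave the NF-kB, mitosis and stress lists an adjusted p of 0.743 each. Fry gave adjusted p values of 0.134, 0.329 and 0.22 for them. The stress list also ended at 0.0965 on quantile-normalised values and 0.0624 on ranks; the cause was not tested. With 1 array left out, which assumes that the lone array varies like the other group, the adjusted p of the NF-kB list ranged from 3.04e-11 to 4.48e-08, of the mitosis list from 9.72e-07 to 0.158 (highest without control replicate 2), of the stress list from 0.00228 to 0.482, of the G1/S list from 0.00527 to 0.907 and of the autophagy list from 0.0363 to 0.366 (both lowest without control replicate 2). The trend brought the G1/S (0.0453), mesenchymal (0.013), hypoxia (0.0335) and autophagy (0.00378) lists past the threshold, and the mean of probe sets the mesenchymal (0.00653) and cholesterol (0.0213) lists; the cause was not tested.

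No effect shared by same-numbered arrays was visible, as their deviations correlated at -0.0265 across genes. The labels do not say whether same-numbered arrays were prepared together. With the replicate number as a block 0 genes passed, with 892 at an unadjusted p under 0.05, and 3 lists passed, the stress list at an adjusted p of 0.0439; the block changed no call. Of 333 alternatives of lists without a call, 26 had the other direction with no call in either fit, and of 1349 alternatives of 126 named genes, 24 changed sign, with 0 calls. The test of 3' UTR seed sites and all its alternatives were not run, since 3' UTR sequences were not used here, and the robust prior was not run for lists, as camera has no such option. Dim genes lie near the floor of these arrays, where differences are compressed, and detection calls were not used here.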

Other observations

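Further gene groups were measured, and none passed with camera in the reported fit. With an intensity trend the autophagy list (camera adjusted p = 0.00378) and the hypoxia list (0.0335) passed. The cholesterol list passed with the mean of a gene's probe sets (0.0213). Autophagy and lysosome genes had 13 of 17 members lower and a median log2 fold change of -0.065 (adjusted p = 0.0791, and 0.0363 without control replicate 2), with LAMP2, a lysosomal membrane protein, at 0.871 and SQSTM1, an autophagy receptor, at 0.892 of the control level. Cholesterol synthesis genes had 10 of 14 lower and a median of -0.068 (0.246), with SC5D at 0.883 and HMGCS1 at 0.889. Hypoxia and glycolysis genes had 13 of 19 higher and a median of 0.03 (0.273), with ANKRD37 at 1.13 and PFKFB4 at 1.09 times. Apoptosis regulators had 12 of 17 lower and a median of -0.04 (0.344), with CFLAR at 0.904 and BCL2 at 1.09 times. Other probe sets of CFLAR were positive in 5 of 8 cases and those of BCL2 negative in 4 of 5.

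Oxidative phosphorylation genes had a median of 0.015 (0.664) and ribosomal protein genes -0.0025 (0.721), heat shock genes -0.0075 (0.721), Wnt targets 0.028 (0.721) and genes of glioma stem and neural progenitor cells 0.06 (0.644). Metallothioneins had a median of 0.005, a mean of -0.0012 and a test direction of down (0.80).

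The following tests of 3 patterns used second gene lists, random lists and splits of the arrays. The second lists were written after the first lists' results were seen and before their own values were looked at; the leukocyte test and the comparison of amino acid genes with chaperones were chosen after the result was seen. For all 3 patterns the 4 arrays allow only 3 splits into pairs, too few for a share under 0.05, and 1 of 3 splits, the real one, gave a statistic as far from 0 in each.

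The NF-kB list was lower in the miR-490 arrays. Its median lay at percentile 0 of 10000 random lists matched on level, whose medians ran from -0.095 to 0.085, which argues against intensity-dependent scaling. The other probe sets of its genes, counted only above the level of the median gene, had a median of -0.17 (SD 0.24, 9 of 10 lower). All 19 genes were lower as well, and both results argue against single faulty probe sets. Leukocyte RNA in the control wells stays open. PTPRC, LYZ and CD14, whose highest control mean was 3.3, had log2 fold changes of -0.16, -0.20 and -0.14, CD3E -0.29 and CD2 -0.26. All of these were dim, with mean levels from 2.43 for LYZ to 3.38 for CD3E, so their differences are weak evidence. CD68 had -0.05, CSF1R -0.015 and CD79A 0.27, and levels of different probe sets cannot be compared. A second list of 36 genes induced by NF-kB and IL-1 was lower too, with 25 negative and a median of -0.068 (camera p = 0.000467; the call was lost with an estimated correlation, p = 0.0555 and adjusted p = 0.0833), led by MMP1 at 0.832 and PTX3 at 0.818 of the control level, with no member past the threshold adjusted over the list alone (smallest adjusted p 0.239), so a wider fall of cytokine-induced genes may be a hypothesis to follow. With 1 array left out, the second list's median ran from -0.0775 to -0.065. The first list's statistic was 8.19 in the real split and 1.7 at most in the others, and differences between wells other than the vector, such as cell density, stay untested.

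The mitosis list was higher in the miR-490 arrays. Its median lay at percentile 100 of the matched random lists, whose medians ran from -0.07 to 0.075, which argues against intensity-dependent scaling. A second list of 39 mitotic genes had 30 higher and a median of 0.08 (camera p = 1.09e-05; the call was lost with an estimated correlation, adjusted p = 0.125), led by DEPDC1 at 1.18 and ASPM at 1.19 times the control level, and no member passed adjusted over the list alone, so a wider rise of mitotic genes may be a hypothesis only. The p of this second list ran from 2.8e-06 to 0.0124 with 1 array left out, highest without miR-490 replicate 1. The first list's statistic was 4.41 in the real split and 2.23 at most in the others. Without control replicate 2 the first list's median was 0.0625, against 0.1 with all arrays. Part of the first list's rise therefore rested on that array, while the second list's median changed little, from 0.08 to 0.075.

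Within the stress list, ASNS, PSAT1, PHGDH, SLC7A11 and TRIB3, grouped as amino acid genes, had a median log2 fold change of -0.25 (-0.37 to -0.17). TRIB3 is not an amino acid enzyme or transporter. The 9 genes grouped as chaperones, which include XBP1, HERPUD1 and EDEM1, had -0.02 (-0.085 to 0.055). The 7 members in neither part included ATF3 at 1.31 times the control level and the co-chaperone gene DNAJB9, with a log2 fold change of -0.18. The highest amino acid gene minus the lowest chaperone was -0.085, but DNAJB9, not counted as a chaperone, lay below PHGDH (-0.17). These genes were also split off after their values were seen. The comparison therefore decides nothing about a general relief of endoplasmic reticulum stress, which stays open. A second list of 32 genes of amino acid supply had 28 lower and a median of -0.068 (camera p = 8.74e-06), led by NUPR1 at 0.856 and MTHFD2 at 0.865; its call was lost with an estimated correlation (p = 0.0365, adjusted p = 0.0833), no member passed adjusted over the list alone (smallest adjusted p 0.333), and its p ran from 1.21e-05 to 0.00123 with 1 array left out. The reason was not tested. The second list's statistic was 4.45 in the real split and 1.08 at most in the others. Among the 3 second lists, fry gave adjusted p values of 0.0214 (NF-kB), 0.1 (mitosis) and 0.0043 (amino acid supply). The second NF-kB and amino acid lists therefore passed with fry, and the second mitosis list did not. In the same order, the estimated correlations of the second lists were -0.0207, 0.0815 and -0.0142, against the preset 0.01.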
